A study of Oryza sativa and Triticum aestivum and Oryza sativa Japonica Group with 26 samples.

How the data were processed

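The series held 26 samples from rice and bread wheat. The files used here were 20 rice peak lists (18 ChIP and 2 input), 3 wheat peak lists and 1 rice RNA count table. The 2 re-sequencing samples of the rice cultivars were not analysed here. Groups were read from the labels, as cultivar and mark for rice and as mark and library treatment for wheat. The labels of the input libraries also list the H3K27me3 antibody, and they were treated as inputs because their titles say so. Rice ChIP and input reads were 51 bp single reads, per the labels' protocols, and wheat reads were paired. Seedlings of wheat were harvested with above-ground and underground parts together, per the labels' protocols.

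Peaks were called with MACS separately for each library, per the file headers. Each peak has a start, an end and a score, a value the authors deposited as the peak caller gave it, on a scale that the file headers do not define. Scores in the deposited lists started at 50, and many peaks sat at a ceiling of 3100. Scores were used only to rank or filter peaks within a list. The RNA values are whole-number read counts per gene ID, as the authors deposited them, in the layout of HTSeq output. The submitters' processing notes name FastQC, BWA, TopHat2 and HTSeq without versions or roles. The genome build, the annotation, the peak threshold and the control library behind each peak list are not given in the sources used here. A list called without a control keeps regions that any chromatin library recovers, and a list's covered length depends on sequencing depth, which peak lists do not show. For that reason overlap with the input lists was computed for every result that allowed it.

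Coordinates are given as in the files, counted from 1. Rice lists were all on sequences named 1 to 12, Un and Sy, so the cultivars were compared on these shared coordinates. Wheat chromosomes were split into parts 1 and 2, and wheat positions are given within a part. The length of a sequence was taken as its furthest peak end, 374 Mb over all rice sequences and 14546 Mb over 43 wheat sequences. Distance along wheat chromosomes was measured from the start of part 1 and from the last peak of part 2, over 42 ends, in steps of 10 Mb. Long parts reach past the centromere, so large distances can approach the other end. Of the 42 ends, 24 lie on parts that reach past 300 Mb, and the ratio of outermost to interior cover was also taken over these alone.

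For each library, overlapping peaks were merged and the covered length, the peak number and the widths were taken. Pairs of lists were compared by the base-pair Jaccard index and by the fold of shared bases over those expected from the covered lengths, or within windows of 1 Mb. A peak counted as overlapped when at least 1 bp was shared. Shares of peaks have 95% Wilson intervals, which cover counting error only. Cultivar-specific marking was counted in windows of 1 kb, as windows touched by a peak in every library of a cultivar and in none of the other. This replaced the planned count of genes, because no annotation on the peaks' coordinates was used here, and it was chosen after the files were seen. Long stretches were runs of at least 50 windows without a ChIP peak in any of 9 libraries of a cultivar, with a peak of the other cultivar in at least 20% of the windows, a definition also set after the files were seen. The widest peaks and the chromosome 11 to chromosome 3 ratio were chosen after the values were seen as well.

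The RefSeq gene table used for names held 0 IDs of the kind in the RNA table, so gene names, the 11 fixed gene lists and the gene-level results were not used here. Counts per gene ID are given as deposited and as CPM, the share of counts assigned to gene IDs scaled to the usual CPM total. Reads assigned to no feature were 26.1% and ambiguous reads 2.97% of all summary and gene counts, and both were left out of the totals. The limit for a count of 0 was set at 3 counts.

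Covered length and peak number were compared between cultivars with exact two-sided permutation tests, 20 arrangements for 3 libraries against 3 with a smallest p of 0.1, and a smallest p of 0.3333 for 2 against 2. The within-minus-between difference in Jaccard index was tested over the 10 splits of 6 libraries, one-sided. H3K27ac, H3K4me3, H3K36me3, wheat and RNA values are given without a test, a choice made where a group had 1 library. No 2 rice peak lists were identical. The rule for named regions, set before the data were examined, took the 3 peaks of highest score per list and, for cultivar-specific results, the 10 of highest mean best score per direction, applied here to runs of windows. The text names a part of these. The same rule was applied without HHZ H3K27me3 replicate 3, a choice made after the values were seen.

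Alternatives were peaks of score 100 or more, equal peak numbers, an overlap of at least 50%, removal of peaks that overlap a peak of the same cultivar's input, each replicate left out in turn and the replicate number as a block. The labels number replicates 1 to 3 within each group and give no shared batch or day. The window count was tested on simulated data made from an H3K27me3 list, with 3 libraries per cultivar and 200 planted regions per cultivar in 374196 windows. All planted windows were recovered (100%), with 86 HHZ and 61 JZ1560 windows called beside them. Recovery was fixed by the design, since each planted region was in every library of its cultivar and in none of the other. All simulated libraries were random parts of the same list, whereas real HHZ H3K27me3 replicates had Jaccard values as low as 0.103. The windows called beside the planted ones therefore do not measure error in the real counts. Computations used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.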

Results

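Histone modifications were mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in young panicles of 2 field-grown rice cultivars and in seedlings of bread wheat. The rice cultivars were HHZ, an indica cultivar, and JZ1560, a japonica cultivar. Rice peak lists covered 5 marks. H3K4me3 is typically found at the starts of active genes, H3K27ac at active promoters and enhancers, H3K4me1 and H3K36me3 over transcribed gene bodies in plants, and H3K27me3 over genes silenced by Polycomb proteins. HHZ had 3 H3K27me3, 2 H3K27ac, 2 H3K4me1, 1 H3K4me3 and 1 H3K36me3 libraries. JZ1560 had 3 H3K27me3, 2 H3K4me1, 2 H3K4me3, 1 H3K27ac and 1 H3K36me3 libraries. Each cultivar also had 1 input library, chromatin sequenced without enrichment. The wheat material was the cultivar Chinese Spring, with 1 library each for H3K27me3, H3K4me3 and H3K4me3 after DSN treatment, in which a duplex-specific nuclease removes abundant fragments before sequencing. An RNA count table came from JZ1560 panicles and held 7169403 counts over 55986 gene IDs. The peak lists gave no read counts, so the depth of the ChIP libraries is unknown. The labels do not say that replicates came from separate plants, so the p-values measure only the spread between these libraries, which may be technical.

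H3K27me3 covered more of the genome in HHZ than in JZ1560 in these libraries. The mark covered 53.9 ± 6.89 Mb in HHZ (SD, n = 3) and 30.2 ± 13.01 Mb in JZ1560 (SD, n = 3), a ratio of 1.78. HHZ libraries held 18139 ± 7073 peaks and JZ1560 libraries 11688 ± 529 peaks (SD, n = 3 each). The input of HHZ had 22976 peaks over 46.1 Mb and the input of JZ1560 had 22254 peaks over 44.3 Mb. Each HHZ library exceeded each JZ1560 library in both measures, and the exact two-sided permutation test gave p = 0.1 for the covered length and p = 0.1 for the peak number. That is the smallest p that 3 libraries against 3 allow, so neither difference can pass 0.05. HHZ replicate 3, counted here, overlapped the inputs more than it overlapped the other H3K27me3 libraries. Without it the difference in covered length was 26.4 Mb (p = 0.2, exact permutation), and the peak difference dropped from 6451 to 2410 peaks. Without peaks that overlap an input peak the differences were 10.2 Mb (p = 0.3, exact permutation) and 2144 peaks (p = 0.2, exact permutation).

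Most of the H3K27me3 territory of JZ1560 lay inside that of HHZ replicates 1 and 2, which extended beyond it. HHZ replicates 1 and 2 had a base-pair Jaccard index, the shared bases over the bases in either list, of 0.807, and the 3 JZ1560 replicates had a mean of 0.514 (range 0.360 to 0.765). Across cultivars, replicates 1 and 2 of HHZ met the JZ1560 libraries at 0.437 (range 0.228 to 0.608, 6 pairs), and 88.1% of the bases of the shorter list of a pair were shared. Seen from HHZ, 23.3% to 68.2% of the bases of replicates 1 and 2 lay inside a JZ1560 list. HHZ replicate 3 stood apart, with a mean Jaccard of 0.0843 and a highest value of 0.120 with the other 5 H3K27me3 libraries, against 0.344 with the JZ1560 input and 0.286 with the HHZ input. It also reached 0.317 with JZ1560 H3K27ac and 0.288 with JZ1560 H3K4me3 replicate 2. Over all 6 libraries, the mean within cultivars exceeded the mean between cultivars by 0.115, with p = 0.1 in the exact one-sided permutation over 10 splits, the smallest p possible. Without HHZ replicate 3 the difference was 0.151 (p = 0.2, exact permutation), and without JZ1560 replicate 1 it was 0.0667 (p = 0.5, exact permutation). It was 0.0538 without JZ1560 replicate 2 and 0.179 without HHZ replicate 1.

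**Figure D1:**
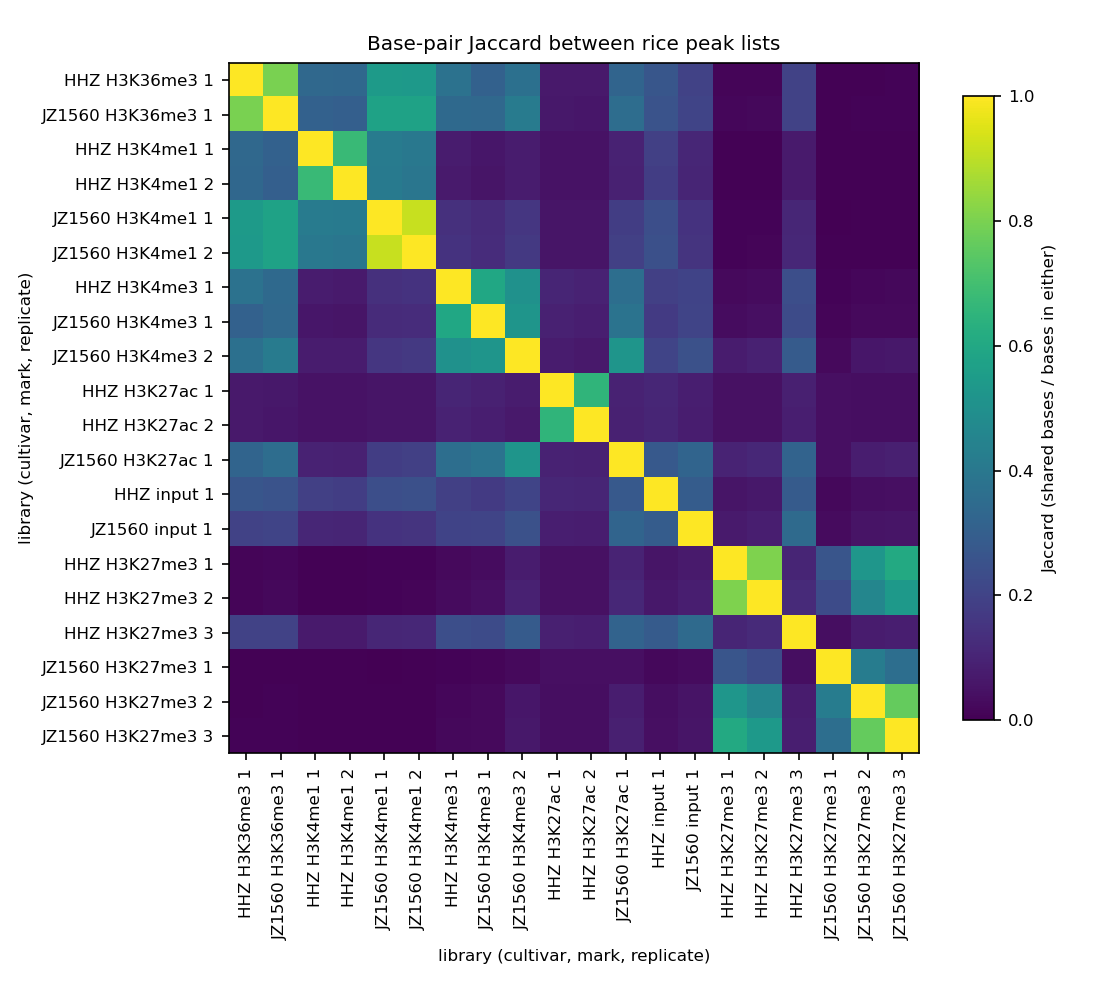
Base-pair Jaccard index (colour, 0 to 1) between each pair of the 20 rice peak lists, named by cultivar, mark and replicate on both axes. HHZ H3K27me3 replicate 3 reaches at most 0.120 with another H3K27me3 library and 0.344 with an input.

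Some H3K27me3 domains were recorded in JZ1560 alone. On chromosome 12, an 18 kb block (22810001 to 22828000) was marked in all 3 JZ1560 H3K27me3 libraries and had a peak in 0 of 9 HHZ ChIP libraries and in neither input. A 9 kb block on chromosome 8 (11372001 to 11381000) and a 5 kb block on chromosome 9 (12111001 to 12116000) had the same pattern, and so did 1 kb blocks on chromosome 12 (19352001 to 19353000) and chromosome 4 (12073001 to 12074000). The JZ1560 block of highest score, 2 kb on chromosome 8 (11036001 to 11038000), had peaks in 2 of 9 HHZ ChIP libraries. HHZ blocks had to be marked in replicate 3 as well, whose peaks overlap the HHZ input. The HHZ blocks of highest score lay where that input had peaks. A 14 kb block on chromosome 4 (19390001 to 19404000) was 98.8% covered by HHZ input peaks and 68.1% by JZ1560 input peaks, and a 3 kb block on chromosome 12 (20647001 to 20650000) was 98.7% covered by HHZ input peaks. Without replicate 3 the 10 HHZ blocks of highest score were others. Among them, 2 kb on chromosome 1 (38596001 to 38598000) had no input peak and had peaks in 4 of 9 JZ1560 ChIP libraries. Blocks of 3 kb on chromosome 6 (9604001 to 9607000) and 4 kb on chromosome 12 (4252001 to 4256000) had no input peak either. HHZ input peaks covered 76.2% of 1 kb on chromosome 4 (17871001 to 17872000). The blocks on chromosomes 6, 12 and 4 had a peak in 0 of 9 JZ1560 ChIP libraries. In 1 kb windows, 4292 were marked in every HHZ and no JZ1560 library, 1471 in every JZ1560 and no HHZ library, and 4780 in all 6, of 133969 marked in any. Without HHZ replicate 3 the HHZ count was 17025, the JZ1560 count 1637, and 20533 of 82833 windows were marked in all 5. With equal peak numbers the counts were 1810 HHZ and 1564 JZ1560 windows. Without peaks that overlap an input peak they were 3169 and 3859. That filter drops each cultivar's peaks by its own input, so a window marked in both cultivars can become specific to 1. The counts after the filter therefore do not show a turn in the balance. The HHZ count was 7815 without HHZ replicate 1, and the JZ1560 count 3412 without JZ1560 replicate 1.

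The widest H3K27me3 peak of each library ranged from 12.6 kb to 49.5 kb, and most of these domains were also marked by H3K27me3 in the other cultivar. The 49.4 kb peak of HHZ replicate 1 on chromosome 5 (6441822 to 6491256) was 48.8%, 90.6% and 98.8% covered by H3K27me3 peaks of the 3 JZ1560 libraries. For the 49.5 kb peak of HHZ replicate 2 on chromosome 3 (6017096 to 6066602) these shares were 80.4%, 94.7% and 96.7%. HHZ replicate 3 covered 7.51% and 18.6% of these 2 regions. The 40.2 kb peak of JZ1560 replicate 2 on chromosome 8 (20045178 to 20085422) lay almost wholly inside peaks of HHZ replicates 1 and 2, and 11.5% of it inside peaks of HHZ replicate 3. The widest peak of JZ1560 replicate 1 was 12.6 kb on chromosome 8 (11024971 to 11037571), with 70.8%, 77.5% and 40.6% covered in the 3 HHZ libraries. A 43.6 kb peak of JZ1560 replicate 3 on chromosome 7 (2386654 to 2430230) differed, with 64.7% and 97.0% covered in the other JZ1560 libraries, 3.48% and 3.81% in HHZ replicates 1 and 2, none in HHZ replicate 3, and no input peak. The widest peak of HHZ replicate 3, 33.4 kb on chromosome 12 (20497696 to 20531135), also lay nearly whole inside a peak of each input. Peak scores are the authors' own values and served here to rank or filter peaks within a list.

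H3K4me1 showed the opposite balance to H3K27me3, with more of the genome covered in JZ1560. The mark covered 27.2 ± 0.400 Mb in HHZ and 63.0 ± 2.34 Mb in JZ1560 (SD, n = 2 each), a ratio of 0.431. HHZ peaks were more numerous and narrower, with 20281 peaks of median width 1097 bp, against 15438 ± 91.9 peaks of 3416 bp in JZ1560. Almost all HHZ territory lay inside the JZ1560 territory, since 95.4% of the bases of the shorter list were shared on average. The Jaccard index was 0.678 between the HHZ replicates, 0.916 between the JZ1560 replicates and 0.404 between cultivars (range 0.393 to 0.414). The 2 cultivars' libraries did not overlap in covered length, and the exact two-sided permutation test gave p = 0.3333, the smallest p for 2 libraries against 2. The difference, HHZ minus JZ1560, was -35.8 Mb with all peaks and -11.1 Mb without peaks that overlap an input peak. That filter drops a whole peak for 1 shared bp, so it takes more bases from wide peaks. By bases, 42.2% of HHZ and 22.1% of JZ1560 H3K4me1 territory lay inside input peaks (means over libraries). The smaller difference therefore does not measure how much is background.

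A large share of the H3K4me1 territory was recorded in JZ1560 only. Peaks of score 100 or more made up 45.2% of the HHZ lists and 93.1% of the JZ1560 lists (means, n = 2 each). The windows cannot tell a mark that is absent from one that stayed below the peak threshold. Of 82650 windows of 1 kb with the mark in any library, 28843 (34.9%) were marked in both JZ1560 and no HHZ library, 1048 in both HHZ and no JZ1560 library, and 34739 in all 4. JZ1560 blocks of high score included 6 kb on chromosome 8 (16946001 to 16952000), 2 kb on chromosome 1 (37190001 to 37192000) and 7 kb on chromosome 7 (3650001 to 3657000). The chromosome 8 block had no input peak, whereas HHZ input peaks covered 43.4% of the chromosome 1 block and 34.9% of the chromosome 7 block. HHZ blocks included 5 kb on chromosome 4 (19392001 to 19397000) and 6 kb on chromosome 9 (13608001 to 13614000), which HHZ input peaks covered by 100% and 90.5%. Without peaks that overlap an input peak the counts were 17550 JZ1560 windows and 8792 HHZ windows. This filter can make a window marked in both cultivars specific to 1, so the higher HHZ count is not added marking. The HHZ count was 1636 without HHZ replicate 1, 1825 without HHZ replicate 2, 328 among peaks of score 100 or more and 633 with equal peak numbers.

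H3K36me3 had the highest Jaccard index between the cultivars among the 5 marks, at 0.798. By the share of the shorter list, H3K4me1 was higher (95.4% against 94.7%), and by the fold over covered lengths H3K36me3, at 5.00, was below H3K4me3 (7.92), H3K4me1 (5.67) and H3K27me3 without HHZ replicate 3 (5.87). H3K36me3 covered 62.5 Mb in HHZ and 70.9 Mb in JZ1560 with median widths of 3330 bp and 3305 bp. A 43.5 kb H3K36me3 peak of HHZ on chromosome 2 (15932839 to 15976303) matched a 43.6 kb peak of JZ1560 (15932657 to 15976235), and the same place held the widest H3K4me1 peaks of JZ1560, 43.8 kb and 43.9 kb wide. H3K4me3 had 18741 peaks over 30.1 Mb in HHZ and 21209 and 25645 peaks over 29.3 Mb and 55.9 Mb in the JZ1560 libraries. The Jaccard index was 0.597 and 0.505 across cultivars and 0.521 between the JZ1560 replicates, so the values across cultivars fell on both sides of that between replicates. H3K27ac had the lowest Jaccard index of these 3 marks, with 11.9 ± 0.0894 Mb in HHZ (SD, n = 2) and 67.0 Mb in the JZ1560 library. Peaks of score 100 or more made up 17.5% of the HHZ H3K27ac lists (mean, n = 2) and 76.0% of the JZ1560 list. The HHZ H3K27ac replicates had a Jaccard index of 0.655, against 0.0924 across cultivars, where the difference in list length alone keeps the index low. Of the bases of the shorter list, 79.6% were shared between the HHZ replicates and 56.1% across cultivars. The HHZ H3K27ac lists met the HHZ input at Jaccard values of 0.106 and 0.105, with 46.7% of their bases inside input peaks. Their mean fold over covered lengths was 3.79 with the HHZ input and 3.14 with JZ1560 H3K27ac. The gap therefore cannot be read as a cultivar difference alone. No test was run for these 3 marks, which had 1 library in at least 1 cultivar.

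Within each cultivar, H3K4me3 and H3K4me1 lay mostly inside H3K36me3 territory, and H3K27me3 lay mostly outside it. In HHZ, 84.3% of H3K4me3 bases and 82.9% of H3K4me1 bases were inside H3K36me3 peaks, 5.05 and 4.97 times the share expected from the covered lengths. In JZ1560 these shares were 76.5% and 77.8%, with folds of 4.04 ± 0.744 and 4.11 ± 0.0843 (SD, 2 library pairs each). H3K27me3 overlapped H3K36me3 at 0.141 ± 0.0190 times the expected share (SD, 3 pairs) and H3K4me1 at 0.1004 ± 0.0166 times (SD, 6 pairs) in JZ1560. In HHZ the folds were 0.870 ± 1.21 and 0.562 ± 0.691 with all libraries, and 0.170 and 0.116 without H3K27me3 replicate 3. H3K27me3 and H3K4me3 overlapped at 0.709 ± 0.234 in JZ1560 and 1.64 ± 1.96 in HHZ, where the fold without replicate 3 was 0.506. H3K27me3 and H3K27ac overlapped at 1.198 ± 0.0697 in JZ1560 and 2.11 ± 0.780 in HHZ, where the fold without replicate 3 was 1.60 ± 0.0230 (SD, 4 pairs).

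The input peaks bore on these overlaps. Peaks of the input overlapped H3K4me3 at 3.27 times the expected share in HHZ and 3.30 times in JZ1560. Their folds were 3.79 and 3.41 with H3K27ac, 3.43 and 1.87 with H3K4me1, and 2.99 and 2.34 with H3K36me3. Input peaks overlapped H3K27me3 at 0.848 times in HHZ without replicate 3 and 0.948 times in JZ1560. Removing peaks that overlap an input peak shortens both lists, while the sequence length behind the expected share stays the same. Folds can rise from this alone, also across 1, so folds after the filter do not show overlap freed of input. Without peaks that overlap an input peak, H3K4me3 met H3K36me3 at 12.7 times the expected share in HHZ and 8.63 times in JZ1560. The corresponding folds of H3K4me1 with H3K36me3 were 7.75 and 9.83, and H3K4me3 met H3K27ac at 10.0 in JZ1560. In JZ1560, H3K27me3 then met H3K36me3 at 0.197, H3K4me1 at 0.132, H3K4me3 at 1.15 and H3K27ac at 2.60, and the last of these was 0.837 among peaks of score 100 or more. In HHZ, the folds of H3K27me3 were 1.46 with H3K36me3, 0.575 with H3K4me1, 2.72 with H3K4me3 and 2.71 with H3K27ac, and without replicate 3 as well they were 0.308, 0.0900, 0.854 and 2.58.

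Active marks thinned out from chromosome 3 to chromosome 11, whereas H3K27me3 did not, apart from HHZ replicate 3. H3K36me3 covered 24.3% of chromosome 3 and 9.34% of chromosome 11 in HHZ, and 26.6% and 11.7% in JZ1560. H3K4me1 covered 22.9 ± 0.781% and 11.1 ± 0.551% in JZ1560 (SD, n = 2), while H3K27me3 covered 8.31 ± 3.58% and 7.94 ± 3.45% there (SD, n = 3). The ratio of chromosome 11 to chromosome 3 was 0.876 ± 0.277 over 6 H3K27me3 libraries and 0.413 ± 0.0509 over 12 libraries of the active marks (SD), with 0.279 and 0.290 in the inputs. The exact two-sided permutation test over 18564 arrangements gave p = 7.003e-04. HHZ replicate 3 had a ratio of 0.317, and without it the H3K27me3 mean was 0.988 ± 0.0479 and p = 1.616e-04, the smallest that 6188 arrangements allow in this exact permutation. The chromosome pair was chosen after the values were seen, and libraries of different marks were treated as exchangeable.

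**Figure D2:**
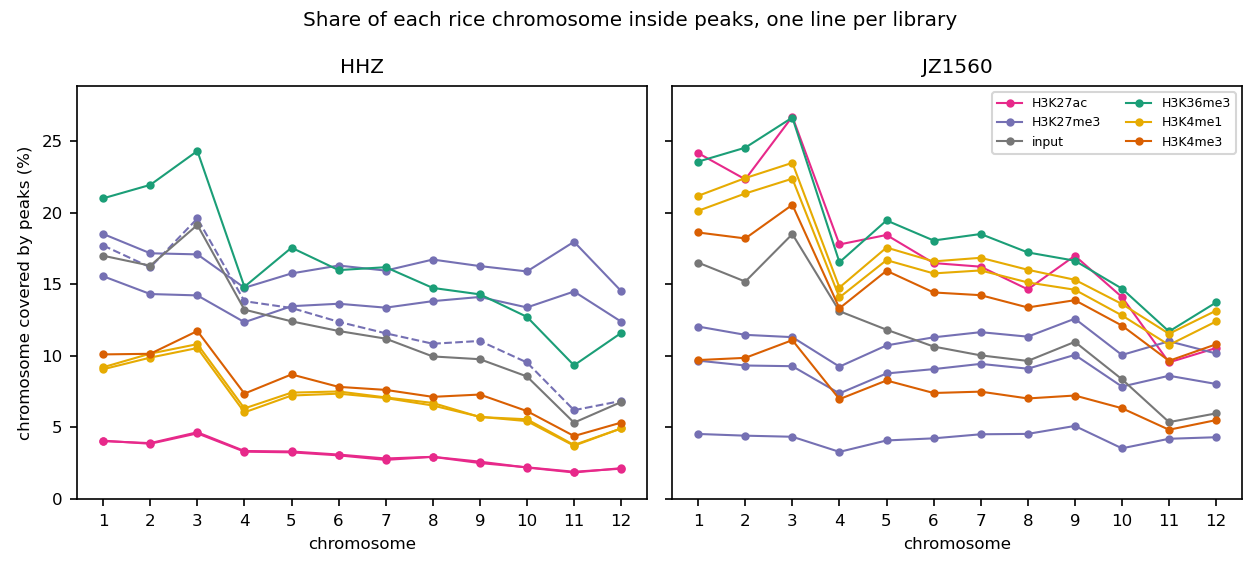
Share of each rice chromosome (x axis, 1 to 12) inside peaks (y axis, percent), one line per library, with HHZ left, JZ1560 right, colour giving the mark and HHZ H3K27me3 replicate 3 dashed. H3K36me3 falls from 24.3% on chromosome 3 to 9.34% on chromosome 11 in HHZ, while the mean of the 3 JZ1560 H3K27me3 libraries is 8.31% and 7.94%.

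In some long stretches only 1 cultivar had peaks of any mark. With a limit of 50 kb without a ChIP peak in 9 libraries of a cultivar and peaks of the other in at least 20% of the windows, 46 stretches (3878 kb) had JZ1560 peaks only and 47 (3599 kb) had HHZ peaks only. Of these 93 stretches, 33 carried peaks of all 5 marks, 9 of H3K27me3 alone (7 of them in HHZ) and 7 of active marks alone, all in JZ1560. JZ1560 stretches included 335 kb on chromosome 7 (27144001 to 27479000), 285 kb on chromosome 12 (8244001 to 8529000) and 82 kb on chromosome 12 (22772001 to 22854000), where 59.8% of the windows had a JZ1560 peak. The last of these contains the 18 kb H3K27me3 block, and 52.4% of its windows carried H3K27me3. In a 59 kb JZ1560 stretch on chromosome 2 (6314001 to 6373000), 50.8% of the windows carried H3K36me3 and 49.2% H3K4me1. HHZ stretches included 285 kb on chromosome 6 (18909001 to 19194000), 139 kb on chromosome 11 (21547001 to 21686000) with H3K27me3 in 41.7% of its windows, and 92 kb on chromosome 1 (22201001 to 22293000). Chromosome 11 held 13 of the HHZ and 9 of the JZ1560 stretches, and chromosome 3 held none. The HHZ input had peaks in 4 windows of the JZ1560 stretches against 308 for the JZ1560 input, and the JZ1560 input in 54 windows of the HHZ stretches against 167 for the HHZ input. The count is a description without a test of single stretches. At a limit of 100 kb it was 7 JZ1560 and 5 HHZ stretches, with 40% of windows carried it was 15 and 7, and among peaks of score 100 or more it was 59 and 37. The HHZ count was 33 without HHZ H3K27me3 replicate 3 and 34 without replicate 2.

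**Figure D3:**
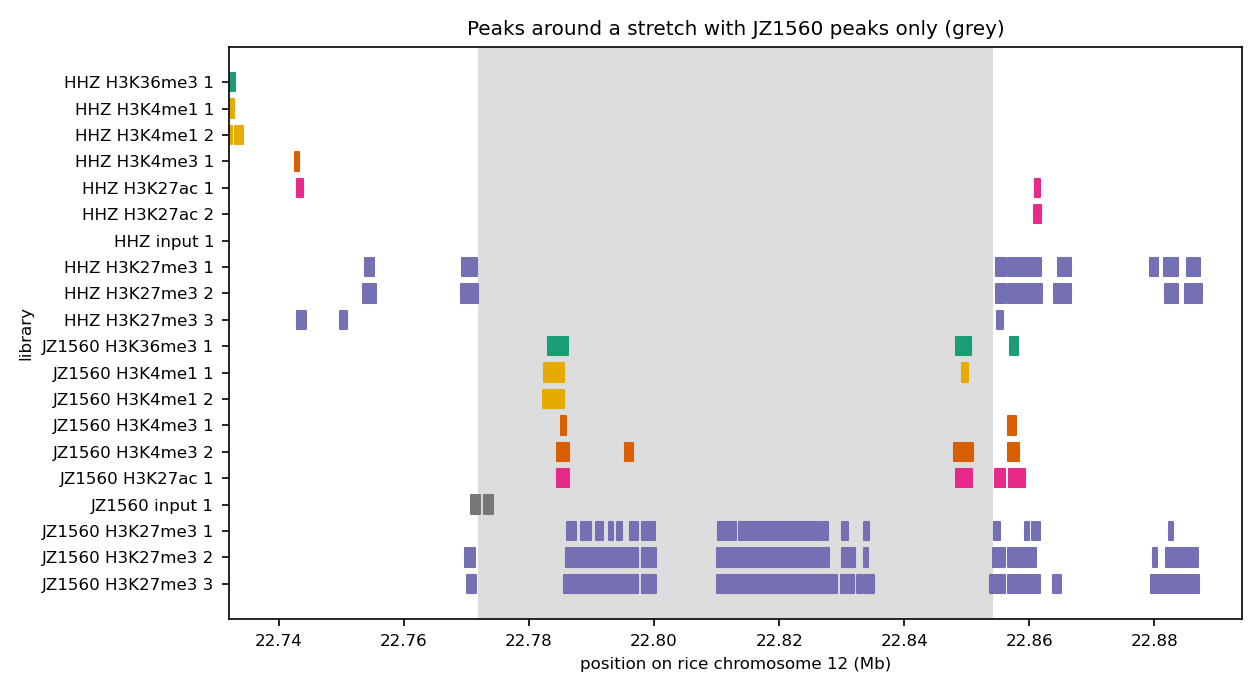
Peaks of the 20 rice libraries (bars, 1 row per library) along chromosome 12 (x axis, Mb) around the stretch from 22772001 to 22854000, shaded grey. None of the 9 HHZ ChIP libraries has a peak in the stretch, while 59.8% of its 1 kb windows carry a peak of a JZ1560 ChIP library.

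The study's design text sets out to rebuild the gene-bearing core of a large genome by joining reads from several marks. Joined over 5 marks with 1 library each, peaks covered 33.4% of the rice genome in HHZ and 33.5% in JZ1560, 125 Mb in each. The unions shared 91.3 Mb, which was 73.1% of the HHZ union and 72.8% of the JZ1560 union. Replicate 1 of each mark was used. In HHZ, H3K36me3 covered 16.7%, H3K27me3 brought the union to 30.1%, and H3K4me3, H3K4me1 and H3K27ac brought it to 31.1%, 32.3% and 33.4%. In JZ1560, H3K36me3 covered 18.9% and H3K27me3 brought the union to 23.1%, while H3K4me1 raised it from 24.1% to 27.5% and H3K27ac to 33.5%. These steps depend on the order of the marks and on the replicate: with H3K36me3, JZ1560 H3K27me3 replicates 2 and 3 gave 27.6% and 29.7%, and HHZ replicates 2 and 3 gave 32.7% and 24.7%. Chromosome 3 was covered most (42.6% in HHZ, 45.3% in JZ1560), against 25.8% and 22.3% of chromosome 11. The unions also held 69.2% of the HHZ and 76.7% of the JZ1560 input peak bases. Without peaks that overlap an input peak they covered 17.0% and 15.8%, and that filter drops a whole peak for 1 shared bp.

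In wheat, H3K27me3 and H3K4me3 peaks shared more bases than their covered lengths alone would give. H3K27me3 had 779349 peaks over 1106 Mb (7.60% of the sequence) with a median width of 1147 bp, and H3K4me3 had 223970 peaks over 713 Mb (4.90%) with a median width of 2707 bp. Of the H3K4me3 peaks, 57.1% overlapped an H3K27me3 peak by at least 1 bp (95% Wilson interval 56.9 to 57.3), and 20.4% of the H3K27me3 peaks overlapped an H3K4me3 peak. The shared bases were 4.17 times those expected from the covered lengths, and 2.88 times those expected within 1 Mb windows. Overlap was most frequent in the middle of the H3K4me3 list, at 75.6% in the third score quintile against 44.7% in the lowest and 53.7% in the fourth. The boundary between the fourth and the highest quintile fell among tied scores of 3100. Among the highest H3K27me3 quintile 54.4% of the peaks met H3K4me3, against 6.76% in the lowest. In rice the fold within 1 Mb windows ranged from 0.394 to 0.917 over the pairs of H3K27me3 and H3K4me3 libraries without HHZ replicate 3, which had 2.99. With 1 wheat library per mark there was no test, intervals cover counting error only, and peaks are not independent. When 50% of the H3K4me3 peak had to be covered, the share was 37.7%, and with equal peak numbers the fold was 7.36.

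Both wheat marks were denser on the D subgenome and towards the chromosome ends. Bread wheat carries 3 related subgenomes, named A, B and D. H3K4me3 covered 4.75% of A, 4.63% of B and 5.59% of D, and H3K27me3 covered 6.99%, 7.59% and 8.17%. The D chromosome was above its A and B counterparts in 7 of 7 homoeologous groups for H3K4me3 and in 5 of 7 for H3K27me3. Chromosome 5D had the highest H3K4me3 cover (6.15%) and 7D the highest H3K27me3 cover (9.73%), and 4B was lowest for both (3.81% and 5.46%). In the outermost 10 Mb of 42 chromosome ends, H3K27me3 covered 23.9% (SD 9.72) against 4.42% between 200 and 300 Mb from the end. The corresponding H3K4me3 values were 10.9% and 2.99%. The ratio of outermost to interior cover was 5.42 for H3K27me3 and 3.65 for H3K4me3. Not every sequence part reaches the interior range, and over the 24 ends that reach through it the ratios were 5.79 and 3.91, with the outermost cover higher at 24 of 24 ends for both marks. The widest H3K27me3 peak spanned 36.3 kb on part 2 of chromosome 1A (81458959 to 81495210), and the widest H3K4me3 peak 30.4 kb on part 2 of chromosome 4A (51628323 to 51658672). The highest scores included an H3K27me3 peak on part 1 of 7A (56908543 to 56915219) and an H3K4me3 peak on part 1 of 5A (205003955 to 205014493). Chromosomes within a library are not replicates, so these values describe single libraries.

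**Figure D4:**
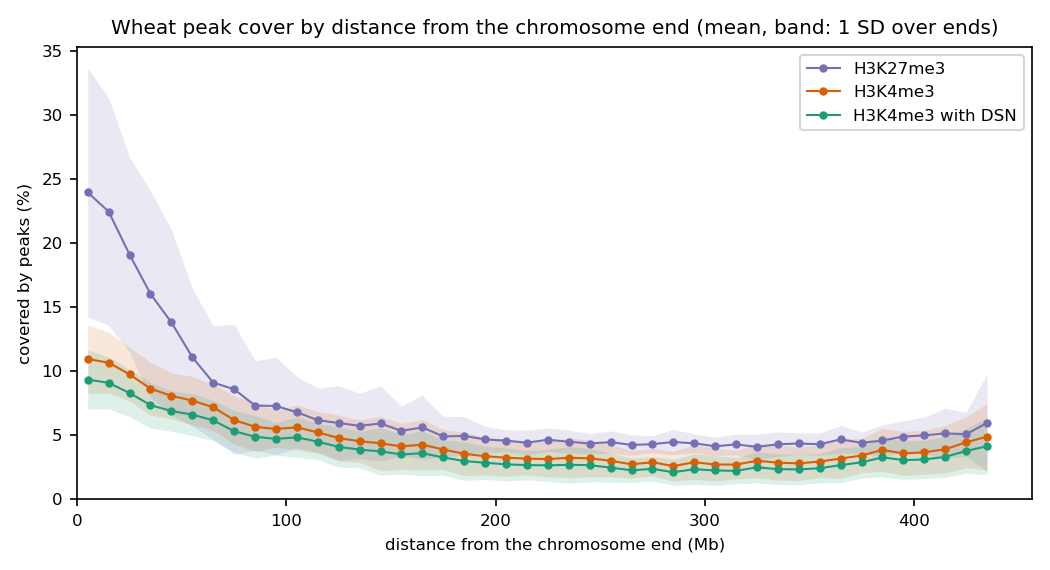
Mean share of wheat sequence inside peaks (y axis, percent) in steps of 10 Mb from the chromosome end (x axis, Mb), one line per library, with bands of 1 SD over chromosome ends. H3K27me3 starts at 23.9% and H3K4me3 at 10.9% in the outermost 10 Mb, against 4.42% and 2.99% between 200 and 300 Mb.

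Strong H3K4me3 peaks of the standard wheat library nearly all recurred in the DSN library, and many weak ones did not. The DSN library had 223666 peaks over 604 Mb (4.15%) with a median width of 2408 bp. Its Jaccard index with the standard library was 0.743, and 94.1% of its peaks overlapped a standard peak (95% Wilson interval 94.0 to 94.2). In the other direction 84.8% of the standard peaks overlapped a DSN peak (84.7 to 85.0), and the 34037 that did not were narrow, with a median width of 1220 bp against 3061 bp for the rest. By score quintile of the standard list, 39.6%, 84.6%, 99.9%, 100% and 100% had a DSN peak. Retention was 85.9% on A, 85.2% on B and 85.4% on D, and 69.3% on unplaced sequence. Another 13144 DSN peaks had no standard peak. Each library was sequenced once, so a repeat of the standard library without DSN was not compared.

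RNA of JZ1560 panicles was spread over many genes. Of 55986 gene IDs, 49514 (88.4%) had at least 1 count and 27514 (49.1%) had 10 or more, with a median of 9 counts. The 10 highest IDs held 4.04% of the counts and the 1000 highest held 35.4%. The highest were LOC_Os09g08910 with 60357 counts (8419 CPM, 0.842% of the counts, 95% Wilson interval 0.835 to 0.849) and LOC_Os12g34108 with 55020 counts (7674 CPM). The files do not pair the IDs with gene names. A count of 0 allows up to 3 counts, or 0.418 CPM, and these intervals and limits cover counting error only. With 1 RNA library there was no comparison between groups.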

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

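The counts in 1 kb windows and their splits were chosen only after the files were seen. The contrasts between marks were read off tables of library values.

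In the rice lists, several marks changed rank between the cultivars, in that every library pair within HHZ went one way and every library pair within JZ1560 the other. The difference between cultivars was not tested for any of them, and 11 of the 20 contrasts examined met this condition. Each of the 11 includes H3K27ac or H3K4me1, so they are not separate results. In HHZ, 17.5% of H3K27ac and 45.2% of H3K4me1 peaks had a score of 100 or more (means). In JZ1560 these shares were 76.0% and 93.1%. Depth is unknown, and the contrasts were not repeated without input-overlapping peaks. In covered length, H3K4me3 was 1.11 times H3K4me1 in HHZ and 0.676 times in JZ1560. H3K4me3 was 2.53 times H3K27ac in HHZ and 0.636 times in JZ1560, and H3K4me1 was 2.29 and 0.940 times H3K27ac. Against H3K27me3, H3K4me1 covered 0.505 times as much in HHZ and 2.09 times in JZ1560, and H3K27ac covered 0.221 and 2.22 times as much. In peak number, H3K4me3 had 0.924 times as many peaks as H3K4me1 in HHZ and 1.52 times in JZ1560, and 1.77 and 0.852 times as many as H3K27ac. H3K4me1 had 1.92 times as many peaks as H3K27ac in HHZ and 0.562 times in JZ1560, and 1.24 and 0.832 times as many as H3K36me3. H3K27ac had 0.648 times as many peaks as H3K36me3 in HHZ and 1.48 times in JZ1560, and 0.583 and 2.35 times as many as H3K27me3. All of the contrasts with H3K27ac rest on 1 JZ1560 library of that mark, those with H3K4me3 on 1 HHZ library, and those with H3K36me3 on 1 library in each cultivar.

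Windows of 1 kb marked in all H3K27me3 libraries of one cultivar and none of the other numbered 5763 in the real split. Of the 10 splits of the 6 libraries, 1 gave as many, the real one, and the highest other split gave 4696. Without HHZ replicate 3 the values were 18662 and 6245. For H3K4me1, 1 of the 3 splits of the 4 libraries gave as many as the real 29891, and the highest other split gave 205. In both marks the splits are too few for a share under 0.05.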

How the results depend on the processing

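Of 192 alternatives over 34 results, 53 moved the value and 5 turned a fold across 1; the cause was not tested. The other 134 kept direction and, for tested results, the side of 0.05, and otherwise stayed within the spread or 1.5 times a count. The spread was an SD over library pairs or chromosome ends, or a counting interval where there was a single library or pair. In HHZ, H3K4me3 with H3K36me3 counted as moved from 5.05 to 5.28. H3K27me3 with H3K4me3 counted as kept from 1.64 to 2.72. The totals therefore mix unlike limits and do not measure robustness. Some of these still changed much in size: without input-overlapping peaks the H3K27me3 differences were 10.2 Mb (from 23.7) and 2144 peaks (from 6451) and the H3K4me1 difference -11.1 Mb (from -35.8), and without HHZ replicate 3 H3K27me3 met H3K36me3 at 0.170 in HHZ (from 0.870). Alternatives on folds without HHZ replicate 3, windows, long stretches, the chromosome ratio, wheat chromosome ends and the 1 Mb expectation were chosen after seeing the data. The input filter drops a whole peak for 1 shared bp, so changes under it do not measure background. The gene-level results and their alternatives (gene overlap, gene lists, expression pseudocount, TPM, count minimum) were not run. The cultivar differences in covered length, peak number and Jaccard index kept their sign under each setting run; with so few libraries their p-values say nothing of stability. Depth is unknown for peak lists, and the RNA depth limits genes with few counts.

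Windows marked in HHZ only by H3K27me3 (4292) were 2473 at score 100 or more, 1810 with equal peak numbers, 2678 with 50% of the window covered, 3169 without input-overlapping peaks, and 4425 to 17025 without each replicate, the highest without HHZ replicate 3 and 7815 without HHZ replicate 1. In JZ1560 only (1471) they were 898, 1564, 1062 and 3859 under the same 4 settings, so the HHZ excess shrank with equal peak numbers. The order without input-overlapping peaks is not read as a result, because that filter can make a window marked in both cultivars specific to 1. The JZ1560 count was 1481 to 3412 without each replicate, the highest without JZ1560 replicate 1. H3K4me1 windows in HHZ only (1048) were 328, 633, 629 and 8792 under these 4 settings and 1106 to 1825 without each replicate; in JZ1560 only (28843), 17550 without input-overlapping peaks.

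Without input-overlapping peaks, HHZ folds were 12.7 (H3K4me3 with H3K36me3), 7.75 (H3K4me1 with H3K36me3), 5.07 (H3K4me3 with H3K27ac) and 1.46 (H3K27me3 with H3K36me3, from 0.870). JZ1560 folds were 8.63, 9.83 and 10.0 for the first 3 pairs, 0.197 (H3K27me3 with H3K36me3), 0.132 (with H3K4me1), 1.15 (with H3K4me3, from 0.709) and 2.60 (with H3K27ac). At score 100 or more, HHZ folds were 5.28, 5.47 and 5.13 for the first 3 pairs and 3.03 for H3K27me3 with H3K27ac; JZ1560 folds were 4.22 (H3K4me1 with H3K36me3), 0.113 (H3K27me3 with H3K36me3) and 0.837 (H3K27me3 with H3K27ac, from 1.198). Without HHZ replicate 3, H3K27me3 with H3K4me3 was 0.506, from 1.64, and 0.854 without input-overlapping peaks as well. The input filter shortens both lists against the same sequence length, so folds under it can rise, also across 1, from the filter alone.

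The union covered 40.6% (HHZ) and 41.0% (JZ1560) with all replicates, 30.9% and 30.4% at score 100 or more, and 17.0% and 15.8% without input-overlapping peaks. Long stretches numbered 7 (JZ1560) and 5 (HHZ) at 100 kb, 15 and 7 with 40% carried, and 59 and 37 at score 100 or more. Without each library they ranged from 44 to 51 and 33 to 61. The lowest HHZ count came without HHZ H3K27me3 replicate 3 and the highest without JZ1560 H3K27me3 replicate 3. In wheat, 97.9% (score 100 or more) and 92.1% (50% overlap) of DSN peaks had a standard peak, and 88.0% and 80.4% of standard peaks a DSN peak. H3K4me3 peaks with H3K27me3 were 48.9% (score 100 or more), 37.7% (50% overlap) and 40.8% (equal numbers), with folds of 5.86 (score), 7.36 (equal numbers) and 2.88 (within 1 Mb).

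Replicate numbers were also used as a block. Same-numbered H3K27me3 libraries did not deviate together (r = -0.0318 for covered length and -0.619 for peak number, 3 pairs), and HHZ replicate 1 overlapped JZ1560 replicate 3 best (Jaccard 0.608), so the numbers were not read as pairs. With the block, the exact sign-flip p was 0.25 for 23.7 Mb and 6451 peaks of H3K27me3 and 0.5 for -35.8 Mb of H3K4me1, each the smallest possible, and the Jaccard differences were 0.160 and 0.394. Leaving out same-numbered pairs gave 7998 (pair 1), 4710 (pair 2) and 23259 (pair 3) HHZ windows and 3509, 1858 and 1648 JZ1560 windows of H3K27me3.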

Other observations

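The comparison of HHZ H3K27me3 replicate 3 with the inputs, the input counts inside long stretches and the use of rice inputs for the wheat overlap were tests chosen only after the results were seen.

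RNA counts in JZ1560 panicles varied between chromosomes. Chromosome 3 had a median of 18 counts per gene ID and 58.8% of its IDs had 10 or more counts, and H3K36me3 covered 26.6% of it in JZ1560. Chromosomes 11 and 12 each had a median of 6 counts per ID, with 42.3% and 41.8% of IDs at 10 or more, and H3K36me3 covered 11.7% of chromosome 11 and 13.7% of chromosome 12. Of all counts, chromosome 1 held 14.0%, chromosome 3 13.4%, chromosome 12 7.64% and chromosome 11 4.50%. These are values of 1 RNA library, with no test.

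Some rice regions had strong peaks under several marks and in the inputs. On chromosome 12, 20497696 to 20531135 carried a 33.4 kb peak in HHZ H3K27me3 replicate 3 and in the HHZ input, and peaks of HHZ H3K27me3 replicates 1 and 2 covered 93.9% and 94.9% of it. The widest H3K4me1 peak (20506392 to 20518800) and the widest H3K27ac peak (20497696 to 20518886) of HHZ replicate 1 lay in the same place. On chromosome 4, 19390001 to 19404000 had peaks in 9 of 9 HHZ and 6 of 9 JZ1560 ChIP libraries, and input peaks covered 98.8% (HHZ) and 68.1% (JZ1560) of it. JZ1560 H3K27me3 replicates 2 and 3 had the same number of peaks, 11383, over 33.2 Mb and 41.4 Mb.

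HHZ H3K27me3 replicate 3 overlapped the other H3K27me3 libraries little (highest Jaccard 0.120). Of its 1000 highest scoring peaks, 30.4% met territory shared by HHZ replicates 1 and 2 (95% Wilson interval 27.6 to 33.3). For the top peaks of the JZ1560 libraries this share was 96.2% to 97.1%. Of the same replicate 3 peaks, 56.1% met HHZ H3K4me3 and 96.9% met the HHZ input. Of the 1000 highest scoring peaks of the HHZ input, 25.4% met that shared H3K27me3 territory and 57.5% met HHZ H3K4me3. The 2 inputs had a Jaccard index of 0.292 with each other. The 30.4% was below the share predicted for a weak but true H3K27me3 library. A poorly enriched library can itself resemble an input, so this share does not decide against one. By fold over covered lengths, replicate 3 met HHZ H3K27me3 replicates 1 and 2 at 1.40 and 1.48. The HHZ input met them at 0.820 and 0.876. A candidate explanation is an input-like or mislabelled library. The lowest Jaccard of replicate 3 with an input exceeded its highest with another H3K27me3 library by 0.166. Whether it is one of these or a weak H3K27me3 library stays open. Its Jaccard with JZ1560 H3K27ac (0.317) and JZ1560 H3K4me3 replicate 2 (0.288) also exceeded that with the HHZ input (0.286). No biological explanation was tested.

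In wheat, H3K27me3 and H3K4me3 peaks shared 4.17 times the bases that covered lengths predict. Regional density at scales of 1 Mb or more as the whole cause is argued against by a fold of 2.88 within 1 Mb windows. Clustering of peaks at a finer scale was not examined and stays open. Weak peaks near the threshold are argued against by a fold of 5.86 among peaks of score 100 or more. Background chromatin that any library recovers may add to the overlap: rice input peaks met H3K4me3 at mean folds of 3.27 in HHZ and 3.30 in JZ1560 (lowest library pair 2.99), but no wheat input was analysed here, so this cannot be told apart. Seedlings were harvested with above-ground and underground parts together, so both marks could also come from different tissues or cells. No biological explanation was tested, since the design gives no wheat group for one.

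In rice, 93 long stretches had peaks in 1 cultivar only, against a median of 9 and a highest count of 61 in the other splits of libraries within marks. Chance in how the libraries were grouped is argued against, since 1 of the 100 splits, the real one, gave as many. Chance is not excluded, because the definition was set after the files were seen and replicates may be technical. Sequence that is missing or diverged in a cultivar may leave both ChIP and input without peaks, and the input of the cultivar without ChIP peaks had 0.122 times as many windows with peaks as the other input (0.0130 times in JZ1560 stretches and 0.323 times in HHZ stretches). Marks may instead differ over sequence that both cultivars carry: relative to other long runs without ChIP peaks, that input's share of windows was 1.30 times as high for the JZ1560 input and 0.458 times for the HHZ input. These cannot be told apart with the inputs, because input peaks mostly lie inside ChIP peaks. The re-sequencing samples of both cultivars, which bear on missing sequence, were not analysed here. A difference between the cultivars' marks stays open as untested.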
